A study of Mus musculus with 4 samples.

How the data were processed

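RNA-seq was measured in 4 libraries of mouse acute myeloid leukemia cells, 2 labelled wild type (WT) and 2 labelled Tet2 knockout. Per the labels, the cells carry NRAS and AML1-ETO9a, were grown in RPMI medium with SCF at 50 ng/ml, IL-3 and IL-6 at 10 ng/ml each, G418 at 1 mg/ml and puromycin at 2 µg/ml, and gave total RNA by QIAzol lysis for a KAPA stranded mRNA kit. Groups and replicate numbers were taken from the sample labels.

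The authors deposited a single table of expression values for the 4 libraries, whose unit was read from the values: each column sums to 1000000 and small values depend on the gene, so they were used as TPM, transcript abundances corrected for transcript length and scaled to that total. Per the submitters' processing notes, STAR, RSEM and the mm10 build were used. Their versions, the annotation and the strand setting were not given in the sources used here. The table holds 24589 entries, of which 92 are ERCC spike-in sequences that share this total with the mouse genes, and 27 are gene names turned into dates, which were not named. Because TPM keep no depth, the number of reads per library is unknown, and no counting interval or detection floor was given. An entry at 0 can be a failed estimate and is reported only as listed at 0. Reads shared by near-identical gene copies, such as the histocompatibility, interferon-induced and eosinophil ribonuclease families, can have been divided between them by the estimator, so values of such genes are uncertain.

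The spike-in entries were left out of the tests. Genes with at least 1 TPM in at least 2 libraries were kept, which left 11837. The deposited TPM were transformed to log2(TPM + 1), with a pseudocount of 1, and compared with limma 3.58.1 in R 4.3.3, using a variance trend, all 4 libraries and no replicate block. Changes are given as knockout-labelled minus WT on that scale, which understates the change of genes at low TPM, with the moderated standard error (SE) and the two-sided p adjusted by the Benjamini-Hochberg method. A gene was called changed at an adjusted p under 0.05. All adjusted p for genes come from this limma fit. The fit had 2 residual degrees of freedom per gene and a prior of 3.51. An exact two-sided permutation test of 2 libraries against 2 cannot go below p = 0.333, so gene calls rest on the spread that limma pools across genes. The labels do not say that replicates came from separate cultures or animals, so the p-values measure the spread between these libraries, which may be technical.

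Before the data were examined, the tests, their alternatives, 30 gene lists and the rule for named genes were fixed. The rule takes Tet2, Tet1, Tet3, Tspan13, Cxcr4 and Ybx1 whatever their values, then the 12 genes with the largest rise and the 12 with the largest fall among called genes whose groups do not overlap and whose higher group averages at least 5 TPM, leaving out predicted and numbered gene models and receptor segments, and up to 4 members of each list with the smallest p, of which part are named. For each list the kept members that rose or fell were counted at the adjusted p over all genes and at a p adjusted over the list alone. The 29 lists with at least 5 kept members were tested with camera at a preset inter-gene correlation of 0.01, which compares a list with the other genes, and adjusted over the lists. Camera with an estimated correlation and fry, which tests whether a list moves on balance in a single direction without comparing it with other genes, were alternatives.

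Alternatives fixed with the tests were a replicate block, quantile and trimmed-mean scaling, no filter, a filter at 5 TPM, pseudocounts of 0.1 and 5, limma without a trend and with robust variances, an adjusted p under 0.01, a minimum log2 change of 1, and leaving out each library. A further 4 were chosen after seeing the data: rescaling without the spike-ins and the 45S pre-ribosomal RNA, rescaling without the granulocyte differentiation list, scaling to the spike-ins, and removing the trend with transcript GC content and length. Another 2 lists, of alternative activation genes and of macrophage markers, were also chosen after seeing the data, as were groups of ribosomal protein and histone genes.

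Coordinates, GC content and length came from GENCODE mouse release 21 on GRCm38, which matched 97.4% of the kept symbols. The limma and camera steps were tested on simulated data for the 11837 genes. Over 10 simulations with 200 changed genes, 50.2% of those shifted by 0.3 on the log2 scale were found. Of those shifted by 1, 96.6% were found, and 8.03% of the calls were false. In the data 30.5% of kept genes were called, a larger part than 200 of 11837, so these shares need not hold there. In the same test, the list of interferon-stimulated genes was shifted by 0.3. It was called in 20 of 20 runs with the preset correlation and in 0 of 20 with the estimated correlation. The latter therefore had little power for that shift at this sample size. With no shift, 1 list was called in 50 runs with the preset correlation. Each simulated gene varied independently of the others, which genes in cells need not do. These runs therefore cannot show how many list calls at the preset correlation are false. Figures were drawn with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.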

Results

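Gene expression was compared between leukemic cells of WT origin and cells labelled as lacking Tet2, a dioxygenase that oxidises 5-methylcytosine. The cells had been derived from bone marrow hematopoietic stem cells and carried NRAS and AML1-ETO9a, a truncated fusion that drives acute myeloid leukemia in mice. The series concerns leukemia stem cell self-renewal and tumor immunity, and the comparison asks which transcripts differ with the Tet2 label in these cells. Each group had 2 libraries (n = 2), and read depth is unknown. Between 11630 and 11731 genes reached 1 TPM per library. Across the 11837 kept genes, which are not independent replicates, Pearson's r was 0.992 within each group and 0.979 to 0.982 between groups.

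Tet2 transcript was present in all 4 libraries and was higher in those labelled knockout. It averaged 37.5 ± 3.46 TPM in WT (SD, n = 2; 35.0 and 40.0) and 53.2 ± 0.52 TPM in the knockout-labelled group (SD, n = 2; 53.5 and 52.8), a log2 change of 0.50 (SE 0.067, adjusted p = 0.0054). Tet2 lies on chromosome 3 from 133463679 to 133545139, minus strand, in GRCm38. The labels place the deletion in exons 8 to 10, which in transcript Tet2-201 are coding, run from exon 8 at 133473596 to 133473685 to exon 10 at 133469276 to 133469639, and make up 592 of 9179 nucleotides (6.45%). A value for the whole gene therefore cannot check the deletion, and every direction below is drawn between libraries by their labels. Tet3 had a log2 change of 0.15 (adjusted p = 0.065), and Tet1 stayed below the filter, with 0.13 and 0.16 TPM in WT and 0.33 and 0.47 in the knockout-labelled libraries.

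In the knockout-labelled libraries, interferon-stimulated genes (35 of 44) and stem cell genes (12 of 25) rose, while genes of granulocyte maturation (29 of 32), MHC class II presentation (9 of 15) and eosinophils (5 of 6) fell. All 5 lists were called by camera at the preset correlation and none with an estimated correlation (lowest adjusted p = 0.36 with an estimated correlation). Of 13 eosinophil markers 6 were kept, and a filter at 5 TPM left 3, too few to test. The largest falls were in Retnla, a secreted resistin-like protein of alternatively activated macrophages (191.8 ± 2.79 to 5.31 ± 0.11 TPM; log2 change -4.93, SE 0.042, adjusted p = 8.2e-07), and Arg1, the arginase of suppressive myeloid cells (409 ± 9.74 to 14.0 ± 0.42 TPM; -4.78, SE 0.040, adjusted p = 8.2e-07; SD, n = 2). Ifitm1, an interferon-induced membrane protein, rose from 301 ± 19.6 to 1008 ± 11.1 TPM (SD, n = 2; 1.74, SE 0.050, adjusted p = 7.5e-05). In all, 3606 genes changed, 2237 higher and 1369 lower, and 79.9% of them by less than 1.5-fold. At a log2 change of at least 1, 66 were higher and 165 lower. All 3606 had groups that did not overlap, as did 68.6% of kept genes. For a single gene chance gives 33.3%, but genes of the same libraries are not independent, so the larger share is not a test. The share of higher calls was 62.0% as deposited, 48.9% with trimmed-mean scaling, 47.3% with the GC and length trend removed, 42.7% with TPM rescaled without the granulocyte differentiation list and 29.9% with spike-in scaling, the last lowering the median of all genes by 0.11 to -0.07. Without replicate 1 or replicate 2 of the knockout-labelled group, 1239 and 1288 genes were called.

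**Figure D1:**
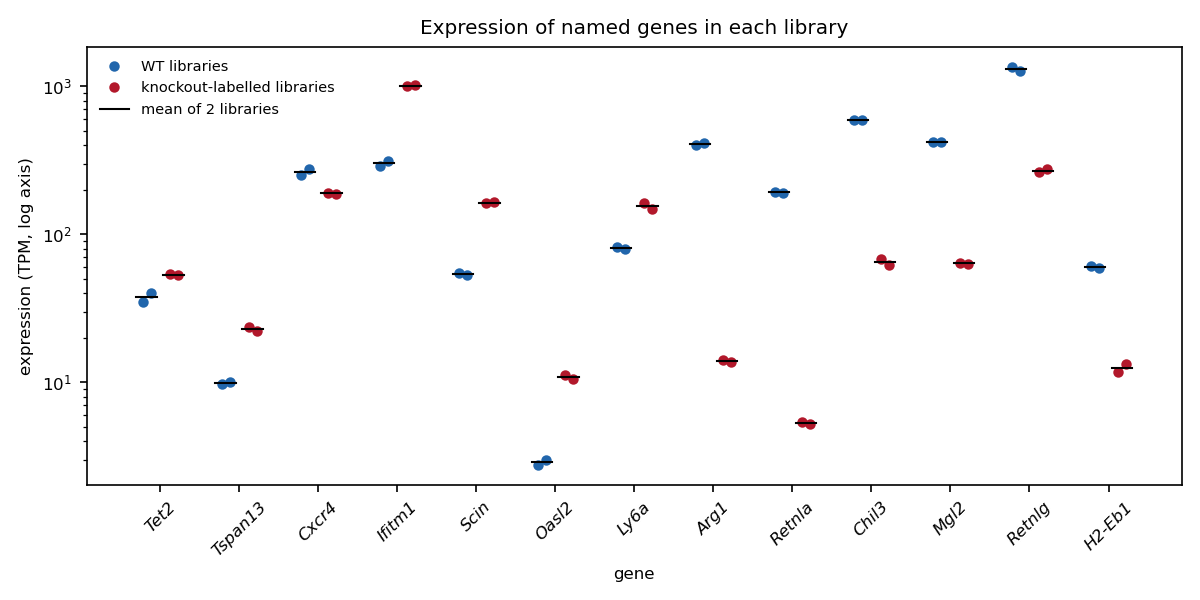
Expression of 13 named genes in TPM on a log axis. Points are libraries, blue for WT and red for knockout-labelled, and black bars are means of 2 libraries; the groups did not overlap for any of these genes, and Tet2 was higher in the libraries labelled knockout.

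Among the genes fixed in advance, Tspan13, a tetraspanin, rose from 9.94 ± 0.17 to 22.9 ± 0.91 TPM (SD, n = 2; log2 change 1.13, SE 0.056, adjusted p = 2.9e-04; chromosome 12, 36014557 to 36042500). Cxcr4, the chemokine receptor that retains progenitors in the marrow, fell from 263 ± 17.3 to 189 ± 1.68 TPM (SD, n = 2; -0.47, SE 0.050, adjusted p = 0.0026; chromosome 1, 128588199 to 128592293). Ybx1, an RNA-binding protein, did not pass (0.10, adjusted p = 0.14), although it did without WT replicate 2 (0.15, adjusted p = 0.022). The other leading rises were in the interferon-induced genes Rtp4 (1.68), Ifi211 (1.61), Oasl2 (1.61), Ifi203 (1.60) and Slfn5 (1.46), and in Cox4i2 (1.72), Scin (1.59) and Gem (1.58). The small nucleolar RNA Snord12 was also listed higher (1.91). The Snord12 call was lost without replicate 1 or 2 of the knockout-labelled group (adjusted p = 0.062 and 0.092), with robust variances (adjusted p = 0.14) and with no filter (adjusted p = 0.057). The Mir1894 call was lost with robust variances (adjusted p = 0.079). The leading falls were in Car4 (-3.56), Ccl24 (-3.42), Chil3 (-3.16), Cyp2a5 (-2.87), Prg2 (-2.80), Mgl2 (-2.70), Il4i1 (-2.68) and Ceacam10 (-2.65). For 4 leading genes a group is listed at 0. Mir6945 (0 and 0 against 5.11 and 13.7 TPM) and Mir1894 (0 and 0 against 8.91 and 2.64 TPM) were listed at 0 in WT. Mir7014 (6.05 and 14.7 against 0 and 0 TPM) and Ndufs5 (9.43 and 5.11 against 0 and 0 TPM) were listed at 0 in the knockout-labelled group. Ndufs5 encodes a subunit of respiratory complex I, which every cell uses, so these zeros can be failed estimates. Snord12, Mir6945, Mir1894 and Mir7014 are annotated as small nucleolar RNA or microRNA genes, while the libraries came from an mRNA kit. Their values are therefore uncertain in both groups.

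Of 25 measured genes of hematopoietic and leukemia stem cells, 12 rose, 1 fell and 12 did not pass. Adjusted over the list alone, 15 rose and 1 fell. Ly6a, which encodes the stem cell antigen Sca-1 and is also interferon-inducible, rose by 0.93 on the log2 scale, Cd34 by 0.46, Angpt1 by 0.85 and Mycn by 1.22. The list was called up by camera (median 0.30, adjusted p = 4.6e-04, or adjusted p = 0.57 with an estimated correlation), with a median of 0.18 with a pseudocount of 5 and 0.16 with no filter. Of 34 genes of homing, adhesion and migration, 10 rose, 13 fell and 11 did not pass. Adjusted over the list alone, 11 rose and 13 fell. The integrin Itgb7 rose by 1.04, while fibronectin (Fn1, -1.47) and Itgb2 (-0.62) fell. The list was not called (adjusted p = 0.12, or 0.031 without WT replicate 1). Its median was -0.06, its mean 0.01 and its test direction down. With spike-in scaling 6 of these genes rose and 13 fell.

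Of 44 interferon-stimulated genes, 35 rose, 0 fell and 9 did not pass. Adjusted over the list alone, 37 rose and 0 fell. Ifi204 (1.21), Oas3 (0.97) and Oas1a (0.63), sensors and effectors of antiviral defence, were among them, and the list was called up (median 0.60, adjusted p = 4.5e-13, or adjusted p = 0.36 with an estimated correlation), with a median of 0.39 with a pseudocount of 5. Of 22 genes of MHC class I presentation, 9 rose, 2 fell and 11 did not pass, with the same counts adjusted over the list alone. The peptide transporter Tap1 (0.46) and the class I gene H2-Q6 (0.98) rose. Its median was 0.11 but -0.01 with spike-in scaling, and its call (adjusted p = 0.040, or adjusted p = 0.47 with an estimated correlation) was lost under 8 other settings, among them without knockout-labelled replicate 1 (adjusted p = 0.080), without WT replicate 2 (adjusted p = 0.12) and with spike-in scaling (adjusted p = 0.12), where 3 rose and 2 fell. Of 15 MHC class II genes, 2 rose, 9 fell and 4 did not pass, with the same counts adjusted over the list alone. H2-Eb1 (-2.18), H2-Aa (-1.85), H2-Ab1 (-1.43) and the invariant chain Cd74 (-0.96) fell, and the list was called down (median -0.38, adjusted p = 4.6e-04, or adjusted p = 0.36 with an estimated correlation). Of 29 immune checkpoint genes, 3 rose, 13 fell and 13 did not pass. Adjusted over the list alone, 4 rose and 13 fell. Beside Arg1, Siglece (-1.57), Lgals3 (-0.69) and Ceacam1 (-0.85) fell, and the list was called down (median -0.17, adjusted p = 0.0022, or adjusted p = 0.59 with an estimated correlation). With spike-in scaling 1 rose and 13 fell, and the median was -0.07 with a pseudocount of 5 or a filter at 5 TPM.

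Of 32 genes of granulocyte differentiation, 29 fell, 1 rose and 2 did not pass, with the same counts adjusted over the list alone. Retnlg (-2.28), Ngp (-1.68) and Wfdc21 (-1.36), products of maturing neutrophils, fell, and the list was called down (median -0.70, adjusted p = 1.6e-23, or adjusted p = 0.36 with an estimated correlation). Its genes held 9.99% and 9.73% of the TPM in WT and 5.82% and 5.86% in the knockout-labelled libraries. Of 18 promyelocyte granule genes, 3 rose, 9 fell and 6 did not pass, with the same counts adjusted over the list alone. Chil3 (-3.16), which had the largest change of the list, neutrophil elastase (Elane, -1.28) and Gstm1 (-1.20) fell. Mpo (0.44), Nkg7 (0.63) and Igfbp4 (0.41) rose. Ctsg and Prtn3 (-0.06 each) did not pass, although Ctsg did with quantile scaling (-0.24, adjusted p = 0.013). The list was called down (median -0.13, adjusted p = 0.0013, or adjusted p = 0.36 with an estimated correlation). Its median was -0.24 with spike-in scaling. Among 31 monocyte, macrophage and dendritic cell markers, 7 rose, 15 fell and 9 did not pass, with the same counts adjusted over the list alone. The mannose receptor Mrc1 (-2.08), the lectin Clec7a (-1.89) and Itgax (-1.40) fell (list called down, median -0.17, adjusted p = 4.6e-04, or adjusted p = 0.36 with an estimated correlation). Among 23 mast cell and basophil markers, 5 rose, 11 fell and 7 did not pass, with the same counts adjusted over the list alone. The mast cell enzymes Hdc (-1.09), Tpsb2 (-1.63) and Cma1 (-1.50) fell, whereas Ifitm1 rose. The list was called down (median -0.27, adjusted p = 0.0080, or adjusted p = 0.59 with an estimated correlation), a call lost with a filter at 5 TPM (median -0.03, adjusted p = 0.051). Of 6 eosinophil markers, 5 fell and 1 rose, also adjusted over the list alone. Beside Prg2, Ccl6 (-0.50) and Alox15 (-0.90) fell, and Ear2 had 1.28 and 1.30 TPM in WT and was listed at 0 in both knockout-labelled libraries (list called down, median -0.83, adjusted p = 0.0020, or adjusted p = 0.36 with an estimated correlation). The eosinophil median was -0.35 with a pseudocount of 5, -1.23 with a pseudocount of 0.1, and -0.34 with no filter, where 12 genes were kept. A filter at 5 TPM kept 3 of the eosinophil genes, too few to test, of which 2 fell and 1 rose. With spike-in scaling 4 of the monocyte, macrophage and dendritic markers and 3 of the mast cell and basophil markers rose, while 15 and 11 fell.

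**Figure D2:**
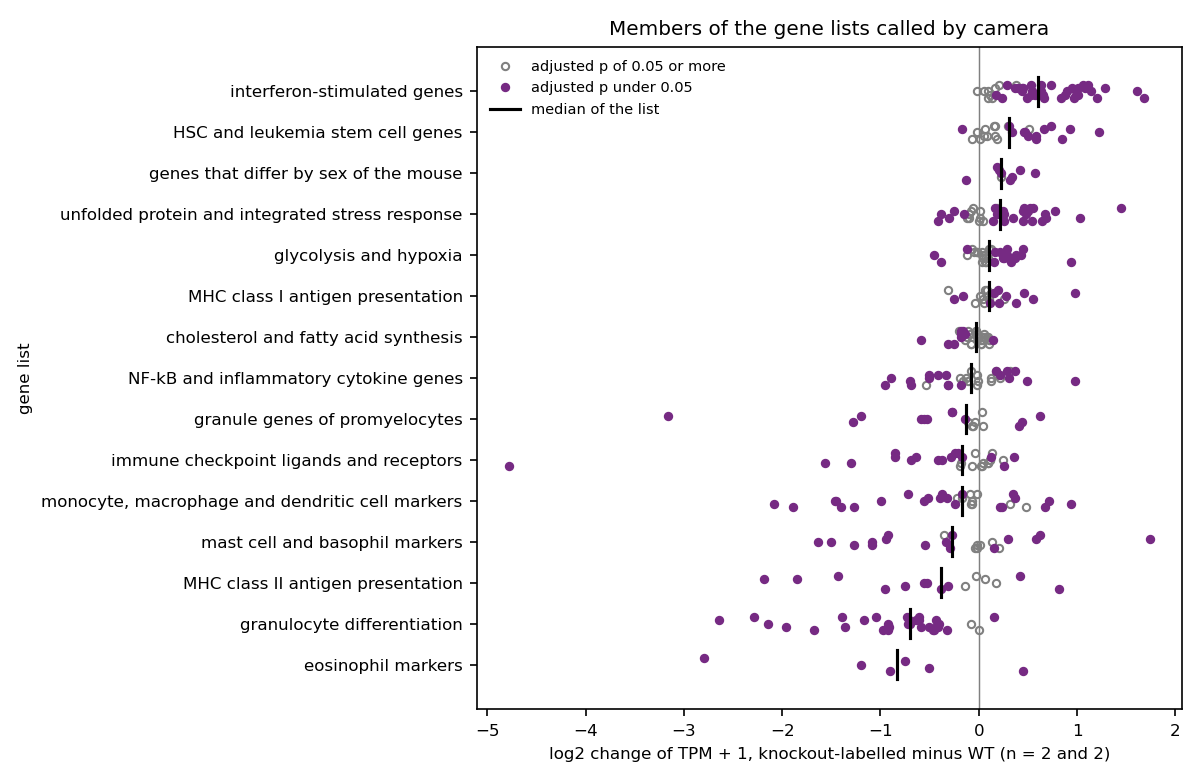
Log2 change, knockout-labelled minus WT, of each kept member of the 15 gene lists called by camera, in units of log2(TPM + 1). Filled points had an adjusted p under 0.05, open points did not, and bars are list medians, from -0.83 for eosinophil markers to 0.60 for interferon-stimulated genes.

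Markers of other lineages went both ways. Most erythroid, lymphoid and stromal markers were not kept: 11 of 28, 8 of 33 and 7 of 21 were. The kept genes therefore need not show that these lineages were present. Of 11 erythroid markers 5 rose and 1 fell, with Car2 at 1.04 and Hbb-bt at 0.65 (adjusted p = 0.34 for the list). Of 17 megakaryocyte and platelet markers 6 rose and 6 fell, or 7 and 6 adjusted over the list alone, with Itga2b at 0.97 and Ppbp at -0.98 (adjusted p = 0.98, median 0.06 and mean 0.10, test direction down). Of 8 lymphoid markers 4 rose and 2 fell, or 5 and 2 adjusted over the list alone, with Thy1 at 0.79, Gzmb at 1.24 and Il7r at -1.15 (adjusted p = 0.13, or 0.031 without WT replicate 1, 0.012 with spike-in scaling, and 0.035 both with the GC and length trend removed and without the granulocyte list). Of 7 stromal and endothelial markers 2 rose and 2 fell, or 3 and 2 adjusted over the list alone, with Pecam1 at -0.34 (adjusted p = 0.46). The erythroid counts adjusted over the list alone were again 5 and 1, and with spike-in scaling 3 rose and 1 fell. None of these 4 lists was called by camera with the deposited scaling of all 4 libraries, while fry called the erythroid, lymphoid and stromal lists (adjusted p = 0.022, 0.0037 and 0.017).

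Among signalling and stress genes, 21 of 36 genes of the unfolded protein and integrated stress response rose, 5 fell and 10 did not pass. Adjusted over the list alone, 22 rose and 6 fell. Asns (0.69), Psat1 (0.56), Trib3 (0.77) and the amino acid transporter Slc7a5 (0.68) rose, and the list was called up (median 0.22, adjusted p = 0.0096, or adjusted p = 0.36 with an estimated correlation). Of 33 genes of glycolysis and hypoxia, 15 rose, 3 fell and 15 did not pass, or 15 rose and 4 fell adjusted over the list alone. The glucose transporter Slc2a3 (0.94) and Ndrg1 (0.38) rose. The list was called up with the deposited scaling (median 0.11, adjusted p = 0.0095, or adjusted p = 0.43 with an estimated correlation) but not with spike-in scaling (median -0.01, adjusted p = 0.068), where 4 rose and 2 fell. With that scaling 13 genes of the stress response list rose and 4 fell, with a median of 0.10. Of the same list 20 rose and 9 fell with the GC and length trend removed, and 17 rose and 9 fell without the granulocyte list. Of 33 genes of cholesterol and fatty acid synthesis, 8 fell and 1 rose, also adjusted over the list alone. Fdps (-0.58), which makes farnesyl pyrophosphate, fell. The list was called down (median -0.03, adjusted p = 0.033, or adjusted p = 0.53 with an estimated correlation). That call was lost without replicate 1 of the knockout-labelled group and with fry (adjusted p = 0.059). The median was -0.14 with spike-in scaling, and -0.09 both with the GC and length trend removed and without the granulocyte list. Of 33 NF-kB and inflammatory cytokine genes, 7 rose, 11 fell and 15 did not pass, or 9 rose and 15 fell adjusted over the list alone. The chemokine Ccl4 (-0.95) and Csf1 (-0.69) fell. The list was called down (median -0.08, adjusted p = 0.033, or adjusted p = 0.40 with an estimated correlation). Another 7 settings ended that call. Among them were leaving out knockout-labelled replicate 2, and spike-in scaling (adjusted p = 0.089), where 2 rose and 12 fell. The list median was -0.19 with spike-in scaling, -0.14 without the granulocyte list and -0.02 with no filter.

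Of 26 RAS and MAPK feedback genes, 13 rose and 4 fell, or 16 and 5 adjusted over the list alone. The phosphatases Dusp2 (0.77) and Dusp4 (0.79) rose and Egr2 (-1.52) fell. The list was not called (adjusted p = 0.18), although it was without WT replicate 2 (adjusted p = 0.039) and with the GC and length trend removed (adjusted p = 0.029). With spike-in scaling 2 of its genes rose and 4 fell. Of 22 immediate-early genes, 5 rose and 6 fell, also adjusted over the list alone, with Fosl2 at -0.47 (adjusted p = 0.27). Cell cycle and DNA replication genes mostly did not pass: of 44, 9 rose and 3 fell, or 8 and 3 adjusted over the list alone, with Top2a at 0.20 and Rrm2 at -0.20 (adjusted p = 0.85 for the list). Without either knockout-labelled library neither gene passed (adjusted p from 0.075 to 0.087), and Top2a did not pass with spike-in scaling (0.08, adjusted p = 0.51) or with the GC and length trend removed (0.10, adjusted p = 0.058). The list had 4 higher and 5 lower genes with trimmed-mean scaling, 4 and 4 with the GC and length trend removed, 1 and 7 without the granulocyte list, and 0 and 3 with spike-in scaling. Of 38 MYC targets and ribosome biogenesis genes, 5 rose and 5 fell, or 4 and 3 adjusted over the list alone, with Rrs1 at -0.46 (adjusted p = 0.80, median 0.02, test direction down). Of 40 oxidative phosphorylation genes, 3 rose and 2 fell, or 1 and 0 adjusted over the list alone, with Uqcrc2 at 0.22 (adjusted p = 0.80 for the list, median 0.01, test direction down). Uqcrc2 did not pass without either knockout-labelled library (adjusted p = 0.066 and 0.071) or with spike-in scaling (0.10, adjusted p = 0.40). Of 27 p53 targets, 8 rose and 2 fell, or 9 and 2 adjusted over the list alone, with Perp at 0.48 (adjusted p = 0.34). Of 31 apoptosis regulators, 8 rose and 5 fell, or 10 and 5 adjusted over the list alone, with Bcl2 at 0.76 and Bcl2a1b at -0.77 (adjusted p = 0.98). Fry called the p53 and apoptosis lists (adjusted p = 0.0025 and 0.0032). With spike-in scaling 0 immediate-early genes rose and 6 fell, 0 MYC targets rose and 3 fell, 0 oxidative phosphorylation genes rose and 1 fell, 3 p53 targets rose and 2 fell, and 2 apoptosis regulators rose and 5 fell. Without the granulocyte list, 3 MYC targets rose and 10 fell, 1 oxidative phosphorylation gene rose and 5 fell, and 5 apoptosis regulators rose and 5 fell. With the GC and length trend removed, 4 MYC targets rose and 7 fell, 3 oxidative phosphorylation genes rose and 5 fell, and 5 apoptosis regulators rose and 5 fell.

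Of 25 DNA methylation and TET genes, 6 rose and 3 fell, or 9 and 3 adjusted over the list alone. Idh1, which makes the TET cofactor 2-oxoglutarate, fell by 0.62 on the log2 scale, and Idh2, which also makes it, rose by 0.27, a call lost with spike-in scaling (0.15, adjusted p = 0.22). The adjusted p for the list was 0.35. With spike-in scaling 2 of these genes rose and 3 fell. Of 18 writers and readers of RNA cytosine methylation, 3 rose and 1 fell, also adjusted over the list alone, with Ybx3 at 0.23 (adjusted p = 0.84 for the list), a gene call lost without either knockout-labelled library (adjusted p = 0.055 and 0.087) and with spike-in scaling (0.12, adjusted p = 0.33), where 0 genes of the list rose and 1 fell. With the GC and length trend removed 1 of the list rose and 3 fell, and without the granulocyte list 2 rose and 2 fell. Only 2 germline genes silenced by DNA methylation were kept, too few to test, of which Dpep3 (0.56) rose. That call was lost on leaving out any library, with the replicate block (adjusted p = 0.0502), with spike-in scaling (adjusted p = 0.061) and with no filter (adjusted p = 0.071). Of 9 genes that differ by sex of the mouse, 7 rose and 1 fell, or 8 and 1 adjusted over the list alone. The Y-linked Uty (0.57) and the X-linked Eif2s3x (0.23) both rose, so the direction of this list does not point to either sex. The list was called up (median 0.23, adjusted p = 0.015, or adjusted p = 0.65 with an estimated correlation). With spike-in scaling 2 rose and 0 fell, with a median of 0.12. Of the 29 tested lists, 15 were called with the preset correlation, 6 up and 9 down, and 0 with an estimated correlation, where the lowest adjusted p was 0.36. Fry called 19.

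The precursor of ribosomal RNA, Rn45s, also differed between the groups, at 5704 and 4350 TPM in WT and 14263 and 8813 in the knockout-labelled libraries (log2 change 1.17, adjusted p = 0.019). Its call was lost without knockout-labelled replicate 1 or WT replicate 2 (adjusted p = 0.056 in each), with robust variances (adjusted p = 0.16), without a variance trend (adjusted p = 0.051) and with no filter (adjusted p = 0.072), and it was chosen after its values were seen. Spike-in sequences took 2.98% and 3.30% of the TPM in WT and 3.41% and 3.39% in the knockout-labelled libraries. Scaling to them therefore also moves the 2 WT libraries relative to each other. A call lost with spike-in scaling can thus reflect spread within WT as well as a shift between the groups. Rescaling without Rn45s and the spike-ins gave 3682 changed genes.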

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

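The tests of this part were chosen after the excess of higher calls was seen. ERCC spike-in sequences, which were not among the genes tested, took a larger share of the TPM in the libraries labelled knockout, 3.40% on average against 3.14% in WT (SD 0.020 and 0.23, n = 2 each). Both knockout-labelled libraries lay above both WT libraries, a split that chance gives in 33.3% of cases in either direction.

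More genes were called higher than lower (2237 against 1369, 62.0% higher) with the deposited scaling, and the design does not settle why. Abundant granulocyte transcripts held a smaller share in the knockout-labelled libraries, which raises the TPM of other genes, and 42.7% of calls were higher with TPM rescaled without the granulocyte list. With spike-in scaling 29.9% were higher, which could mean less mouse RNA per unit of spike-in, but the labels do not say how spike-in was added. Each of these scalings shifts nearly all genes alike between the groups, by a median of -0.06 and -0.11 on the log2 scale. Spike-in scaling also moves the 2 WT libraries relative to each other, as their spike-in shares were 2.98% and 3.30%. It gave 2119 calls against 3417 without the granulocyte list, so part of its loss of calls can be spread between libraries. Most changes are small, so such a shift by itself lowers the share and decides neither explanation. These explanations and a difference between the genotypes cannot be told apart here.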

How the results depend on the processing

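The tests with spike-in scaling, rescaling without spike-ins and 45S or without the granulocyte list, and the GC and length trend removed were chosen after seeing the data. Tet2 stayed higher and past the threshold in all 17 alternative fits, with log2 changes of 0.36 to 0.59. The 3606 changed genes (2237 higher, 1369 lower) became 1505 (839 and 666) at an adjusted p under 0.01, 231 (66 and 165) at a log2 change of at least 1, both by construction, and 2119 with spike-in scaling (634 higher), 1917 of them shared. Without the granulocyte list there were 3417 (1458 higher), 2825 of them shared. Leaving out a library gave 1239 to 3255 changed, 628 to 2190 higher and 602 to 1065 lower; with a lone library its spread was taken from the other group. Without knockout-labelled replicate 1 or 2 there were 1239 (637 higher, 602 lower) and 1288 (628 higher, 660 lower). Fewer libraries were then fitted. The other alternatives gave 2701 to 3932. With the GC and length trend removed, 2911 of the 3527 calls that could be tested remained. Camera with an estimated correlation called 0 lists against 15, and the other alternatives 12 to 19. The replicate numbers share only a number: same-numbered deviations correlated at -0.11 across genes, and the replicate block gave 3071 changed genes, Tet2 at an adjusted p of 0.0091, and 14 lists, without MHC class I (adjusted p = 0.063), with Dpep3 at an adjusted p of 0.050. Over the called genes named in the text, 41 calls across alternatives were lost, in 12 genes, and 1704 kept, and over the called lists 34 were lost and 250 kept. Results that were not called changed direction as follows, and the cause was not tested. Ybx1 was -0.018 with spike-in scaling (adjusted p = 0.90). Adjusted p for apoptosis regulators were 0.91 with the GC and length trend removed, 0.97 without a variance trend, 0.99 with quantile scaling, 0.93 with the block, 0.99 without the granulocyte list, 0.75 with spike-in scaling and 0.78 to 1.00 without a library. For cell cycle genes they were 0.67 with the GC and length trend removed, 0.45 without the granulocyte list, 0.38 with spike-in and 0.73 with trimmed-mean scaling. For megakaryocyte markers they were 0.096 with fry, 0.91 with the GC and length trend removed, 0.97 without a variance trend, 0.63 without a filter, 0.99 with quantile scaling, 0.95 with the block, 0.71 without the granulocyte list, 0.38 with spike-in and 0.82 with trimmed-mean scaling. Fry gave 0.11 for MYC targets and 0.59 for oxidative phosphorylation, which also turned without WT replicate 1 (0.51, and 0.12 to 0.90 over the libraries left out). RNA cytosine methylation genes turned with spike-in scaling (0.97) and without WT replicate 1 (0.83, and 0.57 to 0.87 over the libraries left out). Read depth is unknown, so what it limits could not be assessed.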

Other observations

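The tests, gene groups and genes of this part were chosen after the values were seen, except the monocyte, macrophage and dendritic list. Genes of alternative (IL-4-driven) macrophage activation fell together in the libraries labelled knockout. Of 28 measured, 25 fell and 1 rose, with a median log2 change of -1.49 (-1.58 with spike-in scaling). Socs1 (0.17, adjusted p = 0.070) and Cish (-0.02, adjusted p = 0.78) did not pass. Beyond those of the report, Cdh1 fell from 39.6 to 12.4 TPM, Slc7a2 from 13.2 to 1.39, Ccl22 from 8.63 to 1.61 and Ccl17 from 7.09 to 0.86. The receptor subunit Il4ra rose from 43.2 to 53.2 TPM, a call lost with spike-in scaling and without knockout-labelled replicate 1 (adjusted p = 0.055). The list holds 10 genes of the lists fixed before. Among its other 18 genes 15 fell and 1 rose. Because members were picked with the values in view, the count is not independent evidence of the direction.

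Of 80 ribosomal protein genes, 56 rose and 2 fell (median 0.21), but 0 rose and 2 fell with spike-in scaling (median 0.09). Their share of the TPM was 14.3% in WT and 16.6% in the knockout-labelled libraries. Of 56 histone genes, 18 rose and 0 fell (median 0.40), and 14 rose with spike-in scaling (median 0.30). Rn45s, which is not an mRNA, was also higher in the knockout-labelled libraries, a call that some settings ended, although an mRNA kit was used. Whether the capture of RNA differed between the groups was not tested, so the histone rise may not be one of expression. Xist and the Y-linked Uty were read in all 4 libraries, Xist at 62.4 TPM in WT and 83.5 in the knockout-labelled group (adjusted p = 0.029). The Xist call was lost without knockout-labelled replicate 1 or 2 (adjusted p = 0.12 and 0.14), with the GC and length trend removed (adjusted p = 0.069), without a variance trend (adjusted p = 0.068) and with no filter (adjusted p = 0.085).

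The fall of alternative activation genes was set against 3 explanations. With the GC and length trend removed the list's median stayed at -1.48, against that trend as the cause. Fewer macrophages of every kind would lower other markers alike. The monocyte, macrophage and dendritic list had a median of -0.17 (SD 0.76, 31 genes, 5 shared), with 7 higher and 15 lower. It was called down by camera at the preset correlation (adjusted p = 4.6e-04). Another 17 macrophage markers not tied to IL-4, 13 of them in lists fixed before, had a median of -0.07, with 5 higher and 3 lower. Both medians lay above that of the alternative activation genes (-1.49), so an equal loss of all macrophages would not give a fall of that size. A smaller loss is not excluded. Less IL-4 or IL-13 made by the cells could lower such genes: Il13 had a log2 change of -0.92 (adjusted p = 0.0037) and Il4 of -0.54 (adjusted p = 0.025), but from 5.08 and 2.23 TPM, and the Il4 call was lost on leaving out any library (adjusted p from 0.056 to 0.10). Not all of the alternative activation list fell: 25 genes did, but Socs1 (0.17) and Cish (-0.02) did not pass. Il4ra rose (0.29), a call lost with spike-in scaling. Lower IL-4 or IL-13 cannot be told apart from other effects of genotype without protein data.

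Tet2 was higher in the libraries labelled knockout. Normalization does not account for it, since the lowest log2 change over 6 other scalings was 0.36. Reads of exons outside the deletion may keep the signal, as exons 8 to 10 are 6.45% of the mRNA, but this does not address why it rose. Exchanged labels cannot be told apart from a rise of the truncated transcript: the ratio of 1.42 was over the whole gene, and no exon values were analysed here.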
